A study of Rattus norvegicus with 9 samples.

How the data were processed

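Total RNA from pooled tissue pieces of E13 rat embryos was labelled with biotin and hybridised to 9 single-colour Affymetrix arrays, per the labels' protocols, 3 each for UB, WD and WD with attached mesodermal cells. The pools held about 100, 100 and 50 pieces. The labels call the samples of a tissue biological replicates, and the p-values measure the spread between such pools. The deposited table gives an intensity for each of 31099 probe sets on each array. Per the submitters' processing notes the software was GCOS, the Affymetrix operating software. Its version, the summary algorithm and its parameters are not given in the sources used here. From the values, the scale is linear and all 9 arrays share the same mean of 2501 intensity units once 2% of probe sets are left out at each end, so the arrays had been scaled to a common trimmed mean. No detection calls were used. A weak signal can therefore not be told from background here, and scaling to a common mean makes each difference relative to the other genes of the array.

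Probe sets were named through the platform table and, by Entrez ID, through the GRCr8 gene table. Of the 31099 probe sets, 57 were array controls, 20826 had 1 gene symbol, 436 several and 9780 none, and 20758 of those with 1 symbol matched by Entrez ID. No gene was named from a probe set with several symbols. Each gene was represented by its probe set with the highest mean log2 value over the 9 arrays. Where other probe sets of a named gene were called, none was called in the opposite direction. Some called genes had another probe set that was not called. In UB against WD these included Etv5, Fam181b, Cdh11, Smoc2, Nid1, Itga6 and Timp3. In WD with mesoderm against WD they included Etv5, Gfra1, Wnt11, Ocln, Itga8, Cdh11, Stmn2, Pfkfb3, Ndrg1, Slit2 and Adamts9. In UB against WD with mesoderm they included Etv5, Cdh11, Synpo, Pfkfb3, Nid1 and Itga6. No genome build is named for the array, and no positions are given.

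The analysis used R 4.3.3 and limma 3.58.1. Values were tested as log2(intensity + 46), the pseudocount being the 10th percentile of all values, so differences of weak genes are understated. A probe set was tested if at least 3 of the 9 arrays lay above that array's 40th percentile, which left 20330 probe sets and 10800 genes. Linear models with group as the only term were fitted to all 9 arrays, with 6 residual and 6.08 prior degrees of freedom and a mean-variance trend. P-values were adjusted by Benjamini-Hochberg within a comparison and called under 0.05. All adjusted p-values of genes come from limma. Differences are given as log2 with their standard errors, the first-named group minus the second. The 3 comparisons share arrays and are not independent.

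Of 25 gene lists fixed in advance, 23 had at least 4 tested members and were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01. The lists of primordial germ cells and skeletal muscle cells had fewer members and were not tested. Members were counted as called over all probe sets and adjusted over the list alone. Of 47 list calls in the 3 comparisons, 24 held with the correlation estimated per list, and the p-value from that test is given beside each list call in the text that was lost with it. The lists share members, such as Wt1, Cdh11, Dcn, Lox and Wnt11. Named genes were, for each comparison, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, 12 fixed genes, and from each list up to 4 members with the smallest p. Symbols with prefixes typical of provisional names, such as LOC, RGD and Rn, were passed over in the ranking of rises and falls. This also left out any established gene whose symbol starts with Rn. Of the 12 fixed genes, Wnt9b, Six2, Foxd1 and Osr1 were matched to no probe set with 1 symbol, and Gdnf was below the filter. Where 5 or fewer members of a list were called, they are named in brackets, and those outside the rule were chosen after their values were seen.

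The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were quantile normalization, median centring, other pseudocounts and filters, other variance models, array weights, a fit of only the 2 groups compared, the replicate number as a block, a 2-fold minimum, the mean of all probe sets of a gene, the estimated correlation, and leaving out each array. Added after the data were seen were a batch term, with arrays of a bioC to bioB ratio above 2 set against the rest, fits within each of these array sets, and the log2 beta-actin 3' to 5' ratio as a covariate. Where neither fit called a result, a change of sign was not counted as a reversal.

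The procedure was tested on simulated data for UB against WD. With 20330 probe sets and 100 changed by each size, 48% of log2 changes of 1 and 83% of log2 changes of 2 were called. In this single run 7.09% of the 141 calls were false, which is too few calls to show an excess over the nominal 5%. Far fewer probe sets were changed than the 6073 called in the data, so the shares recovered do not carry over to that comparison. Camera called the list that had been shifted and 0 of the 22 others. The simulated noise was independent between probe sets, so this cannot show false list calls that correlated genes would give. No pair of replicate arrays was a duplicate, as the median absolute log2 difference between arrays of one tissue was 0.187 to 0.351.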

Results

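Gene expression was measured on 9 single-colour oligonucleotide arrays in total RNA from Sprague-Dawley rat embryos at embryonic day 13. The tissues were of 3 kinds, with 3 arrays each. The Wolffian duct (WD) is the epithelial tube of the embryo from which the kidney's collecting system starts. The ureteric bud (UB) is the outgrowth of that duct that enters the kidney mesenchyme and branches. The remaining kind of tissue was the WD with its attached mesodermal cells (WD with mesoderm, WD_mesoderm). Each array holds a pool of about 100 UBs, about 100 WDs or about 50 ducts with mesoderm, and the labels call the arrays of a tissue biological replicates. The UBs were freed with a light trypsin digestion and the WDs were dissected untreated, so digestion and tissue cannot be told apart. Median signals ran from 534 to 897 intensity units per array, and the number of arrays limits the precision of every value.

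The arrays grouped by tissue. Pearson's r over the 20330 probe sets tested was 0.932 to 0.978 between arrays of one tissue, 0.871 to 0.919 between WD and WD with mesoderm, 0.844 to 0.900 between UB and WD and 0.827 to 0.880 between UB and WD with mesoderm. The first principal component, with 49.1% of the variance, separated UB from the rest, and the second, with 19.7%, separated WD from WD with mesoderm. A technical measure separated all UB arrays from all WD arrays and split those of WD with mesoderm. The signal ratio of the spiked control transcripts bioC and bioB was 2.57 to 3.11 on the 3 UB arrays and 2.98 on WD with mesoderm replicate 3, against 0.915 to 1.24 on the other 5 arrays. The same 4 arrays had the lowest 10th percentiles of signal, 26.9 to 35.4 against 55.8 to 77.2. The 3' to 5' signal ratio of beta-actin, a measure of RNA integrity, was 2.19 to 4.87 on the WD arrays, 1.48 to 2.30 on the UB arrays and 1.47 to 1.92 on the arrays of WD with mesoderm.

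**Figure D1:**
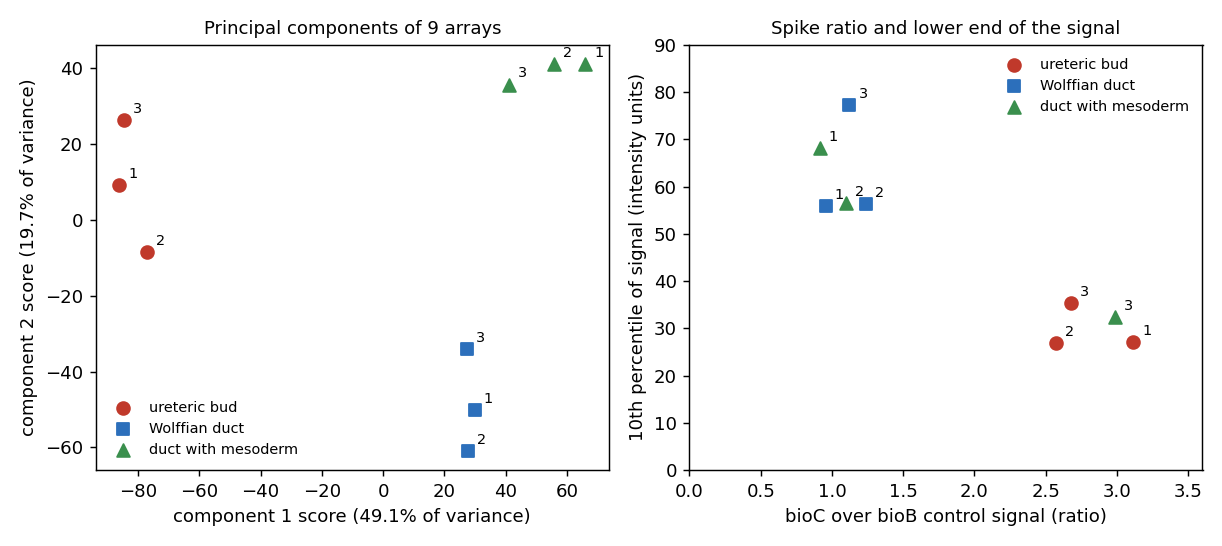
Scores of the 9 arrays on principal components 1 and 2 (left, with the share of variance on each axis), and the 10th percentile of signal in intensity units against the bioC to bioB signal ratio (right). Each point is an array with its replicate number; WD with mesoderm replicate 3, at a ratio of 2.98, lies with the 3 UB arrays in the right panel and with its own tissue in the left.

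The UB was compared with the WD, the tube it grew from. Genes of the bud tip and of GDNF/RET signalling were far higher in the UB, and genes of mesenchyme and its matrix far lower. Wnt11, a secreted Wnt protein made by bud tips, had a mean signal of 3892 ± 1103 in the UB (SD, n = 3) and 25.2 ± 7.79 in the WD (SD, n = 3), a log2 difference of 5.75 ± 0.41 (SE). Etv5 and Etv4, ETS transcription factors that act downstream of RET, rose by 4.01 ± 0.27 and 3.81 ± 0.27. Ret, the GDNF receptor kinase, rose by 2.62 ± 0.20 and Gfra1, its co-receptor, by 1.38 ± 0.18. Of the 14 tip genes measured, 12 rose and 1 fell (Moxd1) over all probe sets, 12 and 1 adjusted over the list alone. The list had a median of 1.94 (camera adjusted p = 1.89e-09). The member that fell, named after its value was seen, was Moxd1 (-2.41 ± 0.23). The other genes with the largest rises were En2, a homeobox transcription factor (5.02 ± 0.37), Cnpy1 (4.77 ± 0.49), Col9a1, a chain of collagen IX (4.72 ± 0.29), the chemokine Cxcl14 (4.70 ± 0.42) and Fam181b (3.80 ± 0.36). En2 and Cnpy1 are direct neighbours in the GRCr8 gene table, with 0 genes between them.

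The general epithelial programme went both ways between UB and WD. Of 27 duct and bud epithelial genes, 6 rose and 7 fell over all probe sets, 7 and 8 adjusted over the list alone. Their median was 0.04 and their mean -0.12, with the test pointing up (camera adjusted p = 0.843), and the median lay just below 0 with quantile normalization, without the filter and without UB replicate 1. Pax2, a transcription factor of the whole duct lineage, differed by 0.29 ± 0.21 (adjusted p = 0.314, limma). A call for Pax2, UB against WD, was reached at 0.0233 with median centring, and the adjusted p ran from 0.0233 to 0.842 over the alternatives. Lhx1 rose by 1.62 ± 0.22. Krt19, a keratin, changed by -4.69 ± 0.16, from 14649 ± 347 in the WD to 524 ± 54.3 in the UB (SD, n = 3 each), Elf5 changed by -2.12 ± 0.26 and the kidney cadherin Cdh16 by -1.75 ± 0.24. Of 4 genes of the bud trunk and urothelium, 0 rose and 3 fell (Gata2, Krt7 and Krt5) over all probe sets, 0 and 4 adjusted over the list alone. The other gene tested was Clu. Most of this list was not tested. Wnt7b and Wnt9b had no match, and Shh, Aqp2, Aqp3 and the uroplakins were not among the genes tested. Over the list the median was -1.65 (camera adjusted p = 0.00536, adjusted p = 0.112 with an estimated correlation). Gata2 changed by -2.08 ± 0.20 and Krt7 by -1.68 ± 0.20. Krt5 differed by -1.61 ± 0.48, but by -0.13 ± 0.71 with the spike batch term. In other settings, the call for Krt5, UB against WD, was lost at 0.157 with quantile normalization, 0.0717 with median centring, 0.0556 without UB replicate 1, 0.0597 without UB replicate 2, 0.0852 without UB replicate 3, 0.946 with the spike batch term, 0.113 with the beta-actin covariate, and the adjusted p ran from 0.0108 to 0.946 over the alternatives.

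Genes of mesenchyme, stroma and mesoderm were lower in the UB. Of 31 mesenchyme and matrix genes, 1 rose (Ptn) and 25 fell over all probe sets, 1 and 27 adjusted over the list alone. As a list they had a median of -2.00 (camera adjusted p = 1.09e-16). Col1a1, a chain of collagen I, had a signal of 304 ± 45.3 in the UB and 8430 ± 1856 in the WD (SD, n = 3 each), and Col3a1 and the proteoglycan Dcn changed by -4.71 ± 0.21 and -5.09 ± 0.21. The member that rose, named after its value was seen, was Ptn (0.93 ± 0.19), which differed by 0.36 ± 0.29 with the spike batch term (adjusted p = 0.569). Of 12 renal stromal genes, 2 rose (Sema3d and Tbx18) and 8 fell over all probe sets, 2 and 9 adjusted over the list alone. The median over members was -2.38 (camera adjusted p = 3.82e-05). Among the members called were Alx1 (-3.73 ± 0.18) and the retinoic acid synthase Aldh1a2 (-3.71 ± 0.20). Of 12 genes of intermediate mesoderm and coelomic epithelium, 0 rose and 7 fell over all probe sets, 1 and 9 adjusted over the list alone. The members had a median of -1.87 (camera adjusted p = 1.75e-05). Wt1 changed by -4.13 ± 0.22 and Osr2 by -5.15 ± 0.25. Large falls were in Bnc1 (-5.95 ± 0.34), the angiotensin receptor Agtr2 (-5.73 ± 0.21), the non-coding RNA Meg3 (-5.55 ± 0.24), Igfbp3 (-5.54 ± 0.24) and Bnc2 (-5.42 ± 0.20). Of 10 nephron and mesonephric tubule genes, 0 rose and 7 fell over all probe sets, 0 and 8 adjusted over the list alone. The typical member stood at a median of -1.98 (camera adjusted p = 1.72e-05). Among the members called were the endocytic receptor Lrp2 (-2.92 ± 0.22) and Podxl (-2.57 ± 0.17). Of 11 nephron progenitor genes, 2 rose (Crym and Meox1) and 5 fell (Itga8, Wt1, Cdh11, Tmem100 and Rspo3) over all probe sets, 3 and 5 adjusted over the list alone. The middle of the list lay at -0.57 (camera adjusted p = 0.0557). The call for the nephron_progenitor list, UB against WD, was reached at 0.00458 with median centring, 0.0271 without UB replicate 1, 0.048 without UB replicate 2, 0.0404 with the spike batch term, 0.0279 with the beta-actin covariate, and the adjusted p ran from 0.00458 to 0.224 over the alternatives, the estimated correlation aside.

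Markers of blood cells and smooth muscle were also lower in the UB than in the WD. Of 10 red cell genes, 0 rose and 8 fell over all probe sets, 0 and 10 adjusted over the list alone. Their median was -2.72 (camera adjusted p = 1.26e-06, adjusted p = 0.134 with an estimated correlation). The embryonic globin Hbz had a signal of 3537 ± 2524 in the UB and 86387 ± 24453 in the WD (SD, n = 3 each), and Ahsp, a haemoglobin chaperone, changed by -5.22 ± 0.38. Of 12 macrophage genes, 0 rose and 5 fell (Lyz2, Csf1r, Cd14, Fcer1g and Ctss) over all probe sets, 0 and 5 adjusted over the list alone. The list had a median of -1.23 (camera adjusted p = 0.0174, adjusted p = 0.202 with an estimated correlation). A call for the macrophage list, UB against WD, was lost at 0.108 with quantile normalization, 0.0825 in a fit of the 2 groups alone, 0.254 with the spike batch term, and the adjusted p ran from 3.77e-04 to 0.254 over the alternatives, the estimated correlation aside. Of 6 smooth muscle genes, 0 rose and 4 fell (Tagln, Mylk, Acta2 and Des) over all probe sets, 0 and 5 adjusted over the list alone. Over the list the median was -1.25 (camera adjusted p = 0.00404, adjusted p = 0.0962 with an estimated correlation). Tagln changed by -2.74 ± 0.36. Of 14 endothelial genes, 1 rose (Cldn5) and 5 fell (Tek, Emcn, Eng, Pecam1 and Esam) over all probe sets, 1 and 6 adjusted over the list alone, and the list as a whole did not pass. As a list they had a median of -0.99 (camera adjusted p = 0.106). In other settings, the call for the endothelium list, UB against WD, was reached at 0.00947 with median centring, 0.0427 without UB replicate 1, 0.0382 without WD replicate 3, and the adjusted p ran from 0.00947 to 0.634 over the alternatives, the estimated correlation aside.

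Cell cycle genes were higher in the UB than in the WD. Of 29 such genes, 22 rose and 0 fell over all probe sets, 26 and 0 adjusted over the list alone. The median over members was 0.65 (camera adjusted p = 2.02e-11). Aurkb, a mitotic kinase, rose by 1.28 ± 0.14 and Mcm3, part of the replicative helicase, by 0.83 ± 0.11. Of 20 hypoxia and glycolysis genes, 11 rose and 2 fell (Vegfa and P4ha1) over all probe sets, 12 and 2 adjusted over the list alone. The members had a median of 0.48 (camera adjusted p = 0.00215, adjusted p = 0.184 with an estimated correlation). Among the members called were the lactate transporter Slc16a3 (1.72 ± 0.19) and the oxygen sensor Egln3 (1.76 ± 0.27). Of 27 immediate early and dissociation stress genes, 8 rose and 3 fell (Ccn2, Hspb1 and Gadd45b) over all probe sets, 13 and 3 adjusted over the list alone. The typical member stood at a median of 0.45 (camera adjusted p = 0.00907, adjusted p = 0.29 with an estimated correlation). The call for the immediate_early_stress list, UB against WD, was lost at 0.066 without WD replicate 2, 0.113 with the beta-actin covariate, and the adjusted p ran from 0.00119 to 0.113 over the alternatives, the estimated correlation aside. The UBs alone were digested with trypsin. Egr2 (2.81 ± 0.39) and Ccn1 (2.08 ± 0.25) were higher in the UB and Ccn2 was lower (-1.51 ± 0.21).

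Secreted signals and matrix genes differed member by member. Of 27 secreted regulators of branching, 7 rose and 9 fell over all probe sets, 7 and 9 adjusted over the list alone. Their median was -0.15 and their mean -0.11, with the test pointing up (camera adjusted p = 0.887), and the median was above 0 with quantile normalization, with median centring and with the spike batch as a term. Npy, a neuropeptide, rose by 2.85 ± 0.17, while Wnt4, a Wnt protein of the condensing mesenchyme, changed by -3.42 ± 0.21 and the Wnt antagonist Sfrp1 by -2.94 ± 0.17. Of 25 basement membrane genes, 4 rose (Itga6, Lama1, Frem2 and Gpc4) and 15 fell over all probe sets, 4 and 16 adjusted over the list alone. The middle of the list lay at -0.62 (camera adjusted p = 0.00426, adjusted p = 0.186 with an estimated correlation). Nid2 changed by -2.43 ± 0.15 and the laminin receptor Itga6 rose by 1.54 ± 0.14. Of 20 matrix proteases and inhibitors, 3 rose (Serpine2, Adamts1 and Adamts9) and 9 fell over all probe sets, 3 and 9 adjusted over the list alone. Their median was -0.67 (camera adjusted p = 0.0199, adjusted p = 0.112 with an estimated correlation). Plat changed by -2.68 ± 0.21 and Mmp2 by -2.34 ± 0.18.

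Over all 20330 probe sets tested, limma called 6073 at an adjusted p under 0.05, 2297 higher and 3776 lower in the UB than in the WD, and 3004 of them differed by at least 2-fold. The 3 UB arrays lay wholly above or below the 3 WD arrays for 47.8% of probe sets, where chance gives 10%. Of the genes with the largest differences, Wnt11, Cnpy1 and Cxcl14 in the WD and Bnc1 and Ahsp in the UB had a signal below the pseudocount of 46 on at least 1 array, so the size and rank of their differences depend on that choice. This split holds relative to equal trimmed means. Of the probe sets called, UB against WD, quantile normalization gave 2525 higher and 2434 lower, and median centring 5843 higher and 1530 lower, with medians of all differences of -0.12, 0.04 and 0.34 in the 3 scalings. With the beta-actin ratio as a covariate 3276 probe sets were called, and without UB replicate 1, 3713. The UB and WD arrays differ in spike ratio without exception, so a batch term can be set only through WD with mesoderm replicate 3. It left 798 calls, 202 higher and 596 lower, of which 789 were among the 6073, and 6002 of the 6073 kept their sign. Among 96 named gene calls 66 were kept with it and among 16 list calls 15. With that term the median of the tip list went from 1.94 to 2.22, of the stromal list from -2.38 to -2.49, of the coelomic list from -1.87 to -2.08 and of the cell cycle list from 0.65 to 0.67. Other called lists came closer to 0, trunk from -1.65 to -1.19, mesenchyme from -2.00 to -1.56, red cell from -2.72 to -2.11, tubule from -1.98 to -1.68, basement membrane from -0.62 to -0.51 and proteases from -0.67 to -0.47. So did macrophage, from -1.23 to -0.62, smooth muscle, from -1.25 to -0.72 (adjusted p = 0.0496), immediate early genes, from 0.45 to 0.23, and hypoxia, from 0.48 to 0.28.

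Genes named above for UB against WD whose calls were lost with the spike batch term follow with the difference, its larger error and the adjusted p under that term. Epithelial and progenitor genes were Krt5 (-0.13 ± 0.71, 0.946), Cdh16 (-1.54 ± 0.44, 0.0853) and Tmem100 (-1.82 ± 0.51, 0.0801). Vessel genes were Tek (-1.34 ± 0.62, 0.281), Emcn (-1.41 ± 0.66, 0.297), Eng (-1.80 ± 0.89, 0.32) and Pecam1 (-1.42 ± 1.07, 0.532). Macrophage and smooth muscle genes were Lyz2 (-1.94 ± 0.62, 0.121), Csf1r (-1.41 ± 0.61, 0.249), Cd14 (-0.92 ± 0.65, 0.493), Fcer1g (-0.90 ± 0.63, 0.491), Acta2 (-0.67 ± 0.41, 0.429) and Des (-0.76 ± 0.41, 0.366). For Mylk they were -1.004 ± 0.35 and 0.157. The others were Mcm3 (0.81 ± 0.21, 0.0557), Ccn1 (1.54 ± 0.42, 0.071), Ccn2 (-1.23 ± 0.39, 0.118) and Slc16a3 (1.31 ± 0.33, 0.0517). Calls of Cd14, Des, Emcn, Fcer1g, Krt5, Pecam1 and Tek, named in brackets above, were lost with quantile normalization.

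**Figure D2:**
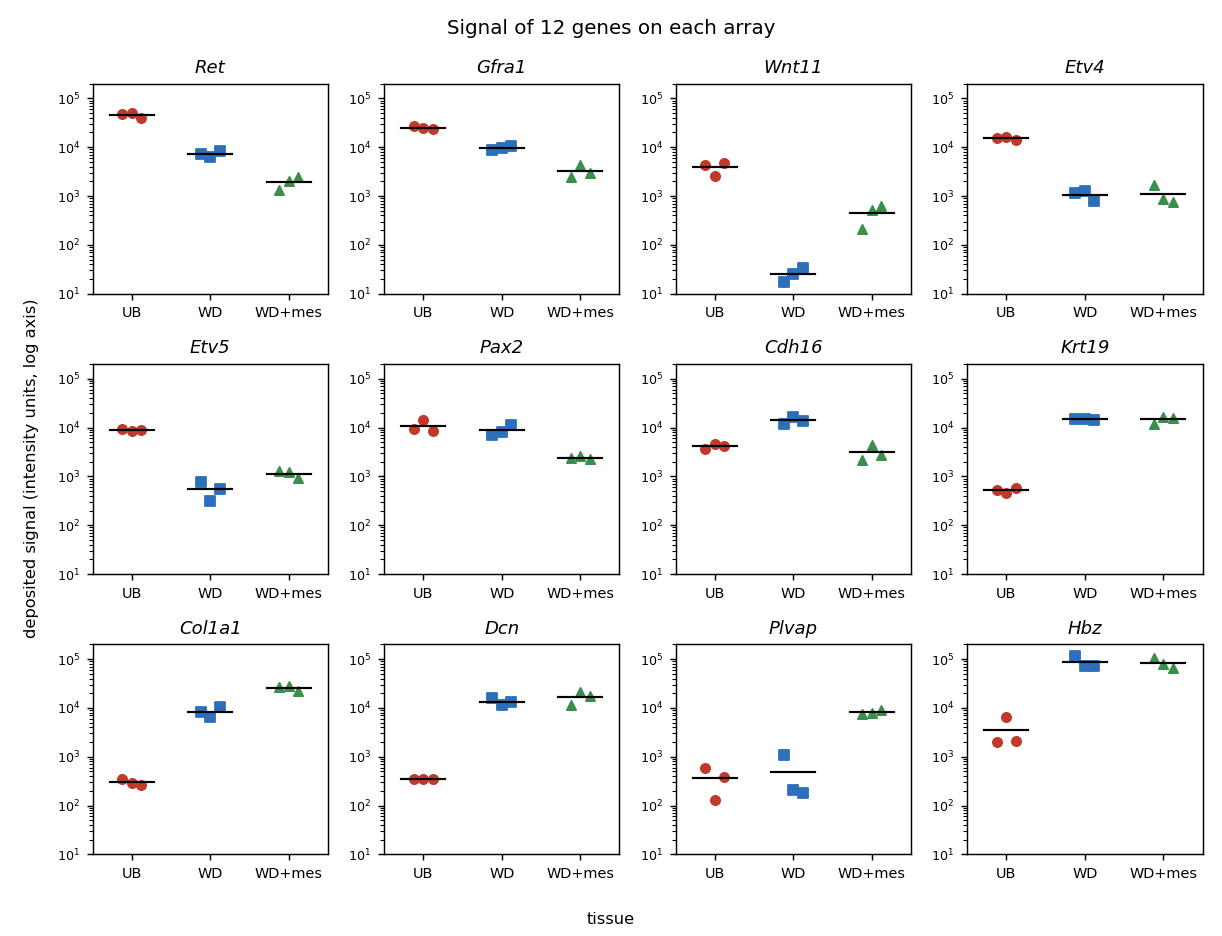
Deposited signal of 12 genes on each of the 9 arrays, in intensity units on a log axis, by tissue (WD+mes is WD with mesoderm); points are arrays and lines the mean of 3. Ret, Gfra1, Wnt11, Etv4 and Etv5 were highest in the UB, Col1a1, Dcn, Krt19 and Hbz were higher in both duct tissues than in the UB, and Plvap was highest in WD with mesoderm.

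The WD with mesoderm was compared with the WD alone, which asks what the attached cells add. Endothelial genes led the rises. Plvap, a protein of endothelial fenestrae, had a signal of 8149 ± 916 with mesoderm and 487 ± 510 without (SD, n = 3 each), a log2 difference of 4.35 ± 0.57 (SE), followed by Klhl4 (4.21 ± 0.60), the chemokine Cxcl12 (3.93 ± 0.20), the endothelial mucin Emcn (3.77 ± 0.35), Shisa3 (3.65 ± 0.46), the transcription factor Sox17 (3.52 ± 0.54), Sox7 (3.39 ± 0.51) and Lrrn3 (3.36 ± 0.47). Of 14 endothelial genes, 12 rose and 0 fell over all probe sets, 14 and 0 adjusted over the list alone. The list had a median of 2.48 (camera adjusted p = 1.13e-13). Among the members called were the VEGF receptor Kdr (3.19 ± 0.28). Of 31 mesenchyme and matrix genes, 18 rose and 0 fell over all probe sets, 24 and 0 adjusted over the list alone. Over the list the median was 0.97 (camera adjusted p = 1.93e-16). Col1a1 rose by 1.62 ± 0.19, Pdgfra by 1.95 ± 0.18 and Vim by 1.86 ± 0.18.

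Other mesodermal groups rose with the attached cells. Of 12 renal stromal genes, 7 rose and 0 fell over all probe sets, 8 and 1 adjusted over the list alone. As a list they had a median of 0.89 (camera adjusted p = 3.90e-05). Meis2 rose by 1.54 ± 0.19. Of 6 smooth muscle genes, 3 rose (Des, Mylk and Tagln) and 0 fell over all probe sets, 4 and 0 adjusted over the list alone. The median over members was 1.28 (camera adjusted p = 4.04e-05). Tagln rose by 2.74 ± 0.36 and Des by 2.08 ± 0.22. Of 11 nephron progenitor genes, 5 rose (Itga8, Crym, Cdh11, Meox1 and Wt1) and 1 fell (Capn6) over all probe sets, 6 and 2 adjusted over the list alone. The members had a median of 0.76 (camera adjusted p = 0.0149, adjusted p = 0.0806 with an estimated correlation). A call for the nephron_progenitor list, WD_mesoderm against WD, was lost at 0.101 with the mean of all probe sets of a gene, and the adjusted p ran from 0.00219 to 0.101 over the alternatives, the estimated correlation aside. Itga8 rose by 1.77 ± 0.18. Of 20 matrix proteases and inhibitors, 8 rose and 1 fell (Adam17) over all probe sets, 9 and 1 adjusted over the list alone. The typical member stood at a median of 0.70 (camera adjusted p = 1.73e-04). Adamts9 rose by 1.74 ± 0.19. Of 12 intermediate mesoderm and coelomic genes, 4 rose (Tcf21, Nr2f1, Wt1 and Wnt5a) and 1 fell (Msln) over all probe sets, 5 and 1 adjusted over the list alone, without a call for the list (camera adjusted p = 0.0684). In other settings, the call for the intermediate_mesoderm_coelomic list, WD_mesoderm against WD, was reached at 0.0392 with median centring, 0.0212 without the filter, 0.014 with the mean of all probe sets of a gene, 0.0452 without WD replicate 1, 0.026 without WD with mesoderm replicate 3, 0.0266 with the spike batch term, 0.0152 on low spike ratio arrays, and the adjusted p ran from 0.014 to 0.159 over the alternatives, the estimated correlation aside. Tcf21, a transcription factor of visceral mesoderm, rose by 3.06 ± 0.29 and Wt1 by 1.15 ± 0.22, whereas the mesothelial protein Msln changed by -2.07 ± 0.23. Of 10 red cell genes 0 were called by limma, also adjusted over the list alone, and 0 had an unadjusted p under 0.05. The list's median was -0.04, its mean 0.07 and its test pointed up (camera adjusted p = 0.754). The call for the erythroid list, WD_mesoderm against WD, was reached at 0.0392 with the beta-actin covariate, and the adjusted p ran from 0.0392 to 0.964 over the alternatives, the estimated correlation aside. That median was above 0 with quantile normalization, with median centring, without the filter, with the batch term and without some single arrays. Of 12 macrophage genes, 1 rose (Mrc1) and 0 fell over all probe sets, 4 and 0 adjusted over the list alone. The middle of the list lay at 0.86 (camera adjusted p = 0.0684). A call for the macrophage list, WD_mesoderm against WD, was reached at 0.0284 with quantile normalization, 0.0337 with the larger pseudocount, 0.0286 without the filter, 0.0105 in a fit of the 2 groups alone, 0.047 without WD replicate 3, 0.0256 with the spike batch term, and the adjusted p ran from 0.0105 to 0.655 over the alternatives, the estimated correlation aside. Mrc1 rose by 2.42 ± 0.68. In other settings, the call for Mrc1, WD_mesoderm against WD, was lost at 0.108 without a pseudocount, 0.0563 with the replicate block, 0.056 without UB replicate 1, 0.0501 without UB replicate 2, 0.0725 without WD replicate 1, 0.0706 without WD replicate 3, 0.0577 with the spike batch term, 0.184 with the beta-actin covariate, and the adjusted p ran from 0.0113 to 0.184 over the alternatives.

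Epithelial genes were lower in the pieces with mesoderm. These pools hold attached cells beside the duct, and all arrays share a common trimmed mean. A smaller share of duct RNA can therefore not be told apart from lower expression in the duct. The limit holds for every fall in this comparison, here and below, and for rises in UB against WD with mesoderm. Of 27 duct epithelial genes, 0 rose and 24 fell over all probe sets, 0 and 24 adjusted over the list alone. Their median was -1.66 (camera adjusted p = 2.14e-22). Cdh1, the epithelial cadherin, changed by -1.69 ± 0.16, the tight junction protein Ocln by -1.71 ± 0.13, Pax2 by -1.82 ± 0.21, Ret by -1.92 ± 0.20 and Gfra1 by -1.58 ± 0.18. The largest falls included Tjp3, a tight junction protein (-2.76 ± 0.36), and the adhesion molecule L1cam (-2.37 ± 0.24). Krt19 differed by 0.01 ± 0.16 (adjusted p = 0.968). Wnt11 rose by 2.68 ± 0.41, to a signal of 445 ± 209 (SD, n = 3) from a WD signal below the pseudocount, and Etv5 by 1.07 ± 0.27. The other probe set of each was not called. The call for Etv5, WD_mesoderm against WD, was lost at 0.0905 in a fit of the 2 groups alone, 0.055 without WD with mesoderm replicate 1, 0.0642 without WD with mesoderm replicate 2, 0.129 on low spike ratio arrays, 0.116 with the beta-actin covariate, and the adjusted p ran from 0.0068 to 0.129 over the alternatives. Of the 14 tip genes, 3 rose (Wnt11, Moxd1 and Etv5) and 2 fell (Ret and Gfra1) over all probe sets, 4 and 3 adjusted over the list alone, with a median of 0.04 that was below 0 with array weights, without WD replicate 3 and on low spike ratio arrays alone (camera adjusted p = 0.754). Of 4 trunk genes, 0 rose and 2 fell (Krt7 and Clu) over all probe sets, 1 and 2 adjusted over the list alone (camera adjusted p = 0.205). Of 25 basement membrane genes, 3 rose (Lama4, Nid1 and Nid2) and 11 fell over all probe sets, 4 and 14 adjusted over the list alone. The list had a median of -0.60 (camera adjusted p = 0.00341, adjusted p = 0.199 with an estimated correlation). Lama1 and Lama5, epithelial laminin chains, changed by -1.52 ± 0.20 and -1.20 ± 0.13, and Lama4 rose by 1.74 ± 0.24. Of 20 hypoxia and glycolysis genes, 0 rose and 3 fell (Pfkfb3, Ndrg1 and Slc16a3) over all probe sets, 0 and 4 adjusted over the list alone. Over the list the median was -0.28 (camera adjusted p = 0.00548, adjusted p = 0.228 with an estimated correlation).

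Cell cycle genes were slightly higher with mesoderm. Of 29, 6 rose and 0 fell over all probe sets, 7 and 0 adjusted over the list alone. As a list they had a median of 0.28 (camera adjusted p = 4.12e-04, adjusted p = 0.0729 with an estimated correlation). The lists that follow did not pass. Of 27 secreted branching regulators, 9 rose and 4 fell (Sostdc1, Slit2, Nrtn and Bmp7) over all probe sets, 10 and 6 adjusted over the list alone (camera adjusted p = 0.101). Of 27 immediate early genes, 1 rose (Ccn2) and 2 fell (Egr1 and Myc) over all probe sets, 1 and 2 adjusted over the list alone (camera adjusted p = 0.645). Of 10 nephron tubule genes, 3 rose (Wnt4, Dab2 and Synpo) and 3 fell (Aadat, Lrp2 and Jag1) over all probe sets, 4 and 3 adjusted over the list alone (camera adjusted p = 0.754). Bmp2 rose by 1.99 ± 0.22 and Ptn by 1.56 ± 0.19, and Sostdc1, a BMP and Wnt antagonist, changed by -1.79 ± 0.16. Limma called 2578 of 20330 probe sets, 1142 higher and 1436 lower with mesoderm, 1465 of them by at least 2-fold. The groups lay wholly apart for 29.6% of probe sets, against 10% by chance. Signals below the pseudocount on at least 1 WD array affect the size and rank of the rises of Klhl4, Sox17 and Lrrn3. Of the probe sets called, WD_mesoderm against WD, quantile normalization gave 1413 higher and 1434 lower and median centring 1244 higher and 921 lower, with medians of all differences of -0.04, 0.00 and 0.06 in the 3 scalings. On the 5 arrays of the low spike ratio 1379 were called, 590 higher and 789 lower, and with the spike ratio as a batch term 1963. The beta-actin 3' to 5' ratio, highest on the WD arrays, left 826 calls as a covariate, with all 12 list calls and 69 of 91 named gene calls kept. Calls of Clu, Egr1, Myc and Slc16a3, named in brackets above, were lost with median centring, and those of Clu (-0.74 ± 0.27, 0.118) and Myc (-0.60 ± 0.19, 0.0806) with the spike batch term.

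**Figure D3:**
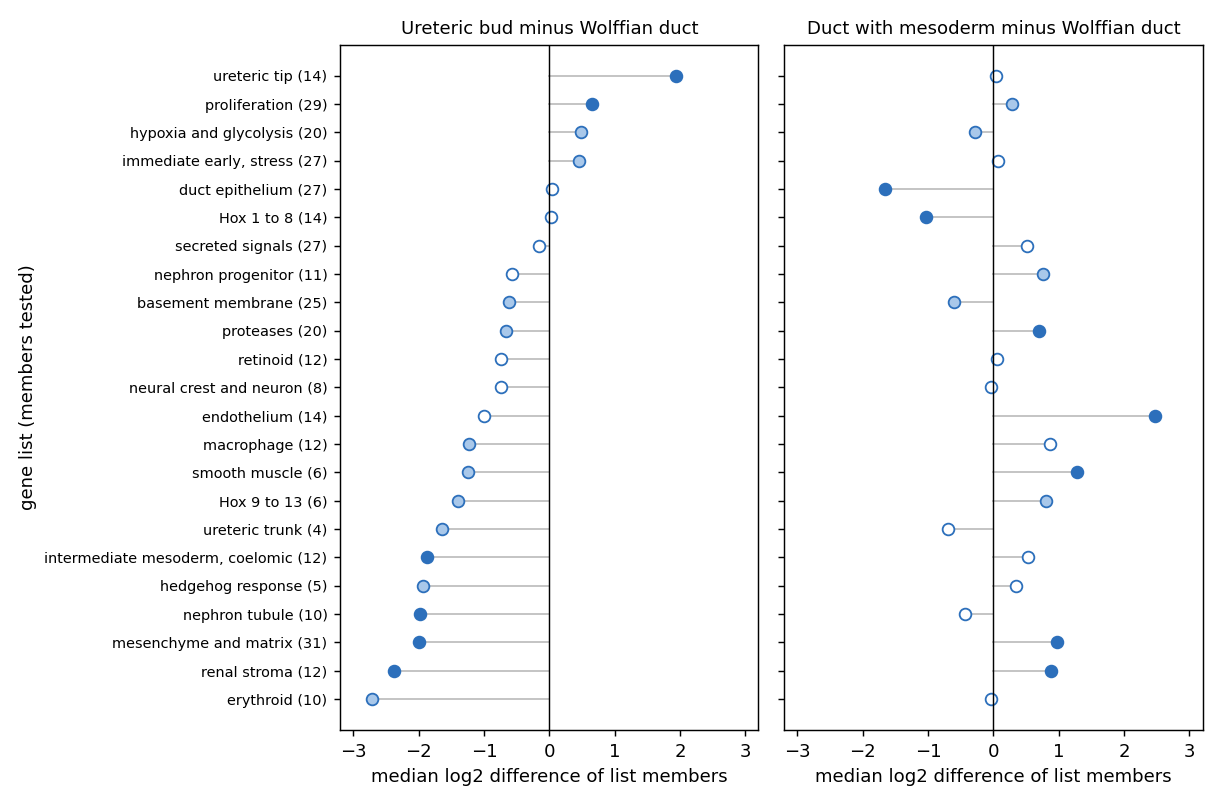
Median log2 difference of the tested members of each gene list for UB minus WD (left) and WD with mesoderm minus WD (right), with the number of members in brackets. Dark points passed camera at an adjusted p under 0.05 with both the preset and the estimated correlation, pale points with the preset one only and open points with neither; endothelial genes had the highest median at right, 2.48, and tip genes at left, 1.94.

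The UB was last compared with WD with mesoderm, which sets the bud against the duct and its surroundings together. En2 rose by 7.18 ± 0.37, Cnpy1 by 6.05 ± 0.49, the potassium channel Kcna2 by 5.00 ± 0.51 and Ret by 4.55 ± 0.20, from a signal of 1937 ± 567 with mesoderm to 45203 ± 5510 in the UB (SD, n = 3 each). Agtr2 (-6.55 ± 0.21), Bnc1 (-6.31 ± 0.34), Igfbp3 (-6.26 ± 0.24) and Col1a1 (-6.20 ± 0.19) fell most. Of 14 tip genes, 12 rose and 1 fell (Moxd1) over all probe sets, 12 and 1 adjusted over the list alone. The median over members was 2.19 (camera adjusted p = 3.71e-08). Of 27 duct epithelial genes, 23 rose and 1 fell (Krt19) over all probe sets, 23 and 1 adjusted over the list alone. The members had a median of 1.66 (camera adjusted p = 9.62e-13). Krt19 changed by -4.70 ± 0.16. Of 31 mesenchyme genes, 0 rose and 30 fell over all probe sets, 0 and 30 adjusted over the list alone. The typical member stood at a median of -3.48 (camera adjusted p = 3.15e-27). All 14 endothelial genes fell, also adjusted over the list alone. The middle of the list lay at -3.38 (camera adjusted p = 2.64e-10). Emcn changed by -5.24 ± 0.35.

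Of 12 stromal genes, 1 rose (Sema3d) and 10 fell over all probe sets, 1 and 10 adjusted over the list alone (camera adjusted p = 2.56e-08). Of 10 red cell genes, 0 rose and 8 fell over all probe sets, 0 and 8 adjusted over the list alone. Their median was -3.12 (camera adjusted p = 8.44e-07, adjusted p = 0.103 with an estimated correlation). Of 12 macrophage genes, 0 rose and 10 fell over all probe sets, 0 and 10 adjusted over the list alone (camera adjusted p = 6.31e-04, adjusted p = 0.0836 with an estimated correlation). Cell cycle genes were higher in the UB. Of 29, 12 rose and 0 fell over all probe sets, 16 and 0 adjusted over the list alone. The list had a median of 0.38 (camera adjusted p = 2.09e-05). Of 20 hypoxia and glycolysis genes, 13 rose and 2 fell (Vegfa and P4ha1) over all probe sets, 13 and 2 adjusted over the list alone. Over the list the median was 0.79 (camera adjusted p = 5.23e-06, adjusted p = 0.0614 with an estimated correlation). Slc16a3 rose by 2.64 ± 0.19. Of 10 nephron tubule genes, 1 rose (Aadat) and 6 fell over all probe sets, 2 and 6 adjusted over the list alone. As a list they had a median of -1.65 (camera adjusted p = 0.00135, adjusted p = 0.0512 with an estimated correlation). Of 27 immediate early genes, 11 rose and 5 fell (Ccn2, Hspb1, Gadd45b, Hspa1a and Hmox1) over all probe sets, 11 and 5 adjusted over the list alone. The median over members was 0.23 (camera adjusted p = 0.0499, adjusted p = 0.414 with an estimated correlation). A call for the immediate_early_stress list, UB against WD_mesoderm, was lost at 0.0535 with quantile normalization, 0.0927 with median centring, 0.0571 with array weights, 0.0726 with the mean of all probe sets of a gene, 0.136 without UB replicate 3, 0.0536 without WD replicate 1, 0.0566 without WD with mesoderm replicate 2, 0.0515 without WD with mesoderm replicate 3, 0.0647 with the spike batch term, and the adjusted p ran from 0.0137 to 0.136 over the alternatives, the estimated correlation aside. Limma called 5176 of 20330 probe sets, 2228 higher and 2948 lower in the UB, and 2980 by at least 2-fold. The groups lay wholly apart for 42.6% of probe sets, against 10% by chance. Signals below the pseudocount on at least 1 array likewise affect Bnc1 in the UB and Cnpy1 and Kcna2 in WD with mesoderm. Of the probe sets called, UB against WD_mesoderm, quantile normalization gave 2307 higher and 2363 lower, and median centring 4610 higher and 1792 lower, with medians of all differences of -0.05, 0.07 and 0.32 in the 3 scalings. With the spike batch as a term 2414 were called. On the arrays of the high spike ratio alone, which hold a single array of WD with mesoderm, 2499 were called, 1287 higher and 1212 lower. That array is assumed to vary like the UB arrays.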

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

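All the tests of explanations in this part were chosen after the result was seen.

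The spiked control transcripts, which were not part of any comparison, drew attention because their balance differs between arrays. The bioC to bioB signal ratio was 3.11, 2.57 and 2.68 on UB replicates 1, 2 and 3 and 2.98 on WD with mesoderm replicate 3, above the highest WD array, at 1.24.

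Dim probe sets were lower on the UB arrays than on the WD arrays. All probe sets, also those below the filter, were split into 4 classes by mean signal. The median difference of UB minus WD was -0.586 in the dimmest class of 7761 probe sets. It was -0.64 in the second class of 7760, -0.178 in the third and 0.074 in the brightest. A candidate explanation is an array run with another background. Within WD with mesoderm, replicate 3, which shares the UB spike ratio, was compared with replicates 1 and 2. Its median difference was -0.519 in the dimmest class, -0.486 in the second, -0.091 in the third and 0.067 in the brightest. This is close to the UB pattern although the tissue is the same. This is a single array, and since no WD array has the high ratio, tissue and run cannot be told apart for the dim probe sets of UB against WD.

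Mesenchyme and matrix genes were lower in the UB than in the WD, with a median of -2.00 over 31 genes. A first test against a run effect, the spike batch term, left a median of -1.56 (camera adjusted p = 1.80e-19). That term rests on 1 array, WD with mesoderm replicate 3. Once its result was known, it was replaced by 10000 random lists matched on mean signal, the lowest of which had a median of -0.595. The list thus fell further than genes of equal mean signal. This cannot decide on a background, since the list had already been called lower against the other genes. The match was also not on UB signal, where its genes can be dim (Col1a1 304 in the UB, 8430 in the WD, 25691 with mesoderm). Weaker RNA on the WD arrays is opposed by a median of -2.02 with the beta-actin ratio as a covariate (camera adjusted p = 1.66e-16). Mesoderm of the makeup of the WD with mesoderm pieces is opposed by its vessels, within a limit given below. The WD held a median share of 0.0970 of the endothelial excess of WD with mesoderm over the UB (14 genes). For mesenchyme the share was 0.405 (29 genes), a difference of -0.308 (permutation test over genes, p = 2.20e-04, BH adjusted 5.50e-04 over 5 lists). The shares of macrophage (0.473, p = 0.566), smooth muscle (0.344, p = 0.646) and renal stromal genes (0.476, p = 0.510) were not called different from that of mesenchyme, as such mesoderm would have it, while red cell genes had a higher share of 0.991 (p = 1.00e-05, the smallest that 100000 permutations can give). These permutation tests count genes as independent units and carry no spread between pools, such as that of Plvap in the WD (1076, 207 and 178). The vessel share thus argues against such mesoderm by its size alone. Mesenchyme genes differed by a median of -0.109 between WD with mesoderm replicate 3, a single array of the high ratio, and replicates 1 and 2. A run effect, particular to these genes, from a background or through dim signals on the UB arrays, stays open. So do mesoderm of another makeup on the WD pieces, expression by the duct itself and the trypsin digestion of the UBs alone.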

How the results depend on the processing

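The spike batch term, the fits within each spike ratio, the beta-actin covariate and the tests on other splits were chosen after the data were seen. None of the 290 calls of named genes and 47 calls of lists changed direction under the alternatives run. Among all probe sets called for UB against WD, 6002 of 6073 kept their sign with the spike batch term. The counts for the probe sets called, UB against WD, the probe sets called, WD_mesoderm against WD, and the probe sets called, UB against WD_mesoderm, moved by more than 1.5 times under these settings. With at least a 2-fold difference required, 3004, 1465 and 2980 probe sets were called for UB against WD, WD with mesoderm against WD and UB against WD with mesoderm, which follows from the stricter rule. With the spike batch as a term, 798 were called for UB against WD and 2414 for UB against WD with mesoderm; this fit sets UB against WD through 1 array and so has wider errors. Fewer arrays entered the fit of low spike ratio arrays, with 1379 for WD with mesoderm against WD, and of high ratio arrays, with 2499 for UB against WD with mesoderm. The beta-actin covariate gave 3276 for UB against WD and 826 for WD with mesoderm against WD, and the cause was not tested. Leaving out each array gave 3713 (without UB replicate 1) to 6400 for UB against WD, 1784 to 2712 for WD with mesoderm against WD, and 3600 to 5337 for UB against WD with mesoderm.

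After group means were removed, same-numbered arrays of different tissues had correlations of -0.348 to 0.277, with 1 of 9 above 0.1. Those of UB with WD were 0.068, 0.093 and 0.277. The lowest involved WD with mesoderm, where replicate 3 stands apart in spike ratio. The check therefore cannot decide whether the numbers pair the samples, and they were not treated as pairs. With the replicate number as a block, 5338 were counted for the probe sets called, UB against WD, 2194 for the probe sets called, WD_mesoderm against WD, and 4606 for the probe sets called, UB against WD_mesoderm. Of 290 named gene calls, 280 were kept with quantile normalization, 278 with median centring, 286 without the filter, 247 with the batch term and 257 with the beta-actin covariate. Of 47 list calls, 45, 45, 47, 45 and 46 were kept in the same settings and 24 with an estimated correlation. Where a fit left fewer probe sets, only those tested in both were counted.

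For each comparison 1 of the 10 splits of the 6 arrays, the real one, gave as many calls. The real counts were 6073, 2578 and 5176, and the highest of the other splits was 0 for each with limma, with 1307, 2283 and 1551 probe sets at an unadjusted p under 0.05 against 8579, 5670 and 7300 in the real splits. Splits of 6 arrays are too few for a share under 0.05. Every other split also mixes both tissues within each group, so the tissue difference widens the spread and few calls were to be had. The low counts of the other splits therefore decide nothing. Without detection calls, the signal over background of weak probe sets was not known, which limits what can be said of them.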

Other observations

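The test of further mesothelial markers was set before their values were seen, while the spike batch term and the beta-actin covariate were chosen after the data were seen.

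Of 6 genes of groups 9 to 13, 0 rose and 5 fell (Hoxa9, Hoxc9, Hoxa10, Hoxd10 and Hoxd9) over all probe sets, 0 and 5 adjusted over the list alone in UB against WD. The list had a median of -1.40 (camera adjusted p = 4.79e-04, adjusted p = 0.125 with an estimated correlation). Hoxa9 changed by -3.63 ± 0.23 and Hoxc9 by -3.84 ± 0.32. In WD with mesoderm against WD, 4 rose (Hoxc9, Hoxa10, Hoxa9 and Hoxd10) and 0 fell over all probe sets, 5 and 0 adjusted over the list alone. Over the list the median was 0.80 (camera adjusted p = 0.00341, adjusted p = 0.185 with an estimated correlation). Hoxc9 rose by 1.55 ± 0.32. With the spike batch term Hoxa9 (0.83 ± 0.27, 0.0794) and Hoxd10 (0.59 ± 0.23, 0.135) lost their calls. Of 14 genes of groups 1 to 8, 1 rose (Hoxa5) and 10 fell over all probe sets, 2 and 11 adjusted over the list alone in that comparison. As a list they had a median of -1.02 (camera adjusted p = 4.04e-05). Hoxb6 changed by -1.68 ± 0.16 and Hoxd8 by -1.18 ± 0.13. In UB against WD this group went both ways, where 2 rose (Hoxb4 and Hoxb7) and 6 fell over all probe sets, 3 and 6 adjusted over the list alone, with a median of 0.02, a mean of -0.55 and a test that pointed down (camera adjusted p = 0.565). The median lay below 0 with quantile normalization, with the batch term, with the beta-actin covariate and without UB replicate 1, WD replicate 1 or WD replicate 3. Hoxa5 (-3.47 ± 0.18), Hoxc8 (-3.38 ± 0.45) and Hoxa7 (-2.27 ± 0.43) fell. With the spike batch term the calls of Hoxc8 (-2.88 ± 0.83, 0.0882), Hoxa7 (-2.85 ± 0.77, 0.071) and Hoxd10 (-1.40 ± 0.37, 0.0651) were lost, each given with its difference, error and adjusted p under that term, and the median of groups 9 to 13 was -1.63. The 2 lists were not tested against each other. In UB against WD with mesoderm, of groups 9 to 13, 0 rose and 6 fell over all probe sets, 0 and 6 adjusted over the list alone. The median over members was -2.26 (camera adjusted p = 8.90e-06, adjusted p = 0.0532 with an estimated correlation). Of groups 1 to 8, 9 rose and 3 fell (Hoxa5, Hoxc8 and Hoxa7) over all probe sets, 9 and 3 adjusted over the list alone. The members had a median of 0.88 (camera adjusted p = 0.00792, adjusted p = 0.0844 with an estimated correlation). In other settings, the call for the hox_anterior list, UB against WD_mesoderm, was lost at 0.0808 with median centring, and the adjusted p ran from 6.40e-05 to 0.0808 over the alternatives, the estimated correlation aside. Their mean was 0.10.

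Retinoid genes differed by member. In WD with mesoderm against WD, Aldh1a1 (-1.89 ± 0.16) and Aldh1a3 (-2.01 ± 0.18), both retinoic acid synthases, fell and the retinoic acid binding protein Crabp1 rose by 1.67 ± 0.21. Of 12 genes there, 3 rose (Crabp1, Crabp2 and Rarb) and 2 fell (Aldh1a1 and Aldh1a3) over all probe sets, 4 and 2 adjusted over the list alone, with a median of 0.06, a mean of -0.04 and a test that pointed up (camera adjusted p = 0.754), and the median was below 0 without the filter. In UB against WD, 1 rose (Rdh10) and 6 fell over all probe sets, 3 and 7 adjusted over the list alone. The typical member stood at a median of -0.74 (camera adjusted p = 0.0575). The call for the retinoid list, UB against WD, was reached at 0.0246 with quantile normalization, 0.0122 with median centring, 0.0398 without UB replicate 1, 0.0411 without UB replicate 3, 0.0203 with the spike batch term, and the adjusted p ran from 0.0122 to 0.0852 over the alternatives, the estimated correlation aside. Crabp1 changed by -2.43 ± 0.21 and Cyp26b1, which degrades retinoic acid, by -1.47 ± 0.20. In UB against WD with mesoderm, 2 rose (Aldh1a3 and Aldh1a1) and 6 fell over all probe sets, 2 and 7 adjusted over the list alone. The middle of the list lay at -0.60 (camera adjusted p = 0.0377, adjusted p = 0.227 with an estimated correlation). A call for the retinoid list, UB against WD_mesoderm, was lost at 0.0561 with the mean of all probe sets of a gene, 0.0524 without WD with mesoderm replicate 2, and the adjusted p ran from 0.0162 to 0.0561 over the alternatives, the estimated correlation aside. Of 5 hedgehog response genes in UB against WD, 0 rose and 3 fell (Gli1, Gli2 and Boc) over all probe sets, 0 and 3 adjusted over the list alone. Their median was -1.93 (camera adjusted p = 0.00616, adjusted p = 0.0937 with an estimated correlation). Gli1 changed by -2.22 ± 0.17, and with mesoderm against WD 1 rose (Boc) and 0 fell over all probe sets, 1 and 0 adjusted over the list alone (camera adjusted p = 0.132). In other settings, the call for the hedgehog_response list, WD_mesoderm against WD, was reached at 0.0493 without WD with mesoderm replicate 3, 0.0499 with the spike batch term, 0.0176 on low spike ratio arrays, and the adjusted p ran from 0.0176 to 0.389 over the alternatives, the estimated correlation aside. Boc rose by 1.37 ± 0.26. Of 8 neural crest and neuron genes, 2 rose (Gap43 and Elavl4) and 1 fell (Stmn2) over all probe sets, 2 and 1 adjusted over the list alone in UB against WD, with a median of -0.74, a mean of -0.06 and a test that pointed up (camera adjusted p = 0.815). Gap43, a growth cone protein, rose by 3.15 ± 0.22. With the spike batch term the hedgehog list had a median of -1.64, and the calls of Gli2 (-1.64 ± 0.42, 0.0557), Elavl4 (1.99 ± 0.56, 0.0819) and Stmn2 (-1.59 ± 0.78, 0.314) were lost.

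Krt19, Msln and Bnc1, taken here as genes of coelomic epithelium, were lower in the UB than in the WD, by log2 differences of -4.69, -2.81 and -5.95. Krt19 was also counted above as a duct and bud epithelial gene. With mesoderm against WD, Msln was called lower (-2.07, limma adjusted p = 1.68e-04), while Krt19 (0.01) and Bnc1 (0.35) were not called. Duct epithelial genes fell there by a median of -1.66, so a level signal does not show that the attached cells lack these genes. A candidate explanation is coelomic epithelium on the WD pieces. A list of 13 other mesothelial markers had a median of -0.951 in UB against WD (1 called higher, Crip1, and 7 lower over all probe sets, 2 and 8 adjusted over the list alone, camera adjusted p = 0.00596, adjusted p = 0.073 with an estimated correlation) and of 0.31 in WD with mesoderm against WD (camera adjusted p = 0.333). In the latter its members went both ways, 3 called higher (Efemp1 1.89 ± 0.23, Sulf1 1.85 ± 0.25, Nkain4 2.90 ± 0.47) and 2 lower (Calb2 -1.65 ± 0.24, Pdpn -0.97 ± 0.16) over all probe sets, 5 and 3 adjusted over the list alone, chosen for naming after their values were seen. Of the 13 genes, 0 also belonged to another list. High signals on the WD arrays came from Igfbp5 (9174, with 2244 in the UB and 11520 with mesoderm), Pdpn (8710, with 2479 in the UB and 4457 with mesoderm) and Calb2 (7025, with 1012 in the UB and 2210 with mesoderm). Signals of different probe sets are not comparable as levels. The first median missed the bound of -1 and the second the bound of 0.3 set for the explanation. The bound of 0.3 made no allowance for a smaller share of duct RNA in the pieces with mesoderm. A bound against it was set for UB against WD alone and included an adjusted p over 0.05, which the estimated correlation gave and the preset one did not, so the test left it open. Expression of these genes by the duct was not tested.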
